A study of Arabidopsis thaliana with 12 samples.

How the data were processed

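RNA from whole seedlings was hybridised to 12 one-colour arrays, 1 per sample, with 2 biological replicates in each of the 6 groups of 3 genotypes and 2 treatments. Per the labels' protocols, plants grew at 22 C under 16 h of light and 8 h of dark, RNA was extracted with Trizol and purified on columns, and cDNA amplified from 10 ug of total RNA was labelled with Cy3. The deposited values are log2 expression values per transcript, made by the authors with RMA per the submitters' processing notes, which give no version. That the scale is log2 was taken from the values, which run from 6.99 to 15.95. Per the file headers each transcript value rests on 1 to 4 probes, and 59 transcripts had 1 probe. RMA corrects background, equalises the distributions of arrays and summarises probes, so a change in total RNA per cell would not be seen, and high values are compressed near the top of the scanner range. The version, the array design and the genome build are not given in the sources used here. The whole-series table held the same values as the single files (largest difference 0 over 445416 values). No background or saturation flags were in the files used here, and array number limits the precision.

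Each array carried 37118 transcripts of 32627 loci. Where a locus had more than 1 transcript feature (3602 loci), the feature with the highest mean over all 12 arrays was used. Names came from the array annotation and from the gene table of assembly TAIR10.1, which held 31993 of the loci and was used for names and neighbours only. A total of 10836 loci had a symbol from either source. No filter on dim loci and no further normalization was applied.

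One limma fit (limma 3.58.1 in R 4.3.3, lmFit and eBayes, no trend) of the 6 group means on all 12 arrays left 6 residual degrees of freedom, so that groups of 2 shared an estimate of the spread. The 9 contrasts were the ABA response in each genotype, each altered line against wild type without and with ABA, and the difference of each altered line's ABA response from that of wild type. Tests were two-sided, with Benjamini-Hochberg adjustment over all loci of a contrast and a threshold of 0.05. The median standard error was 0.21, and 0.14 with the replicate number as a block (5 residual degrees of freedom). The 26 gene lists, with 413 of 414 members kept, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 26 lists, and again with an estimated correlation, with which none of the 9 contrasts kept a called list. The ABA-induced markers, all 28 higher in wild type, missed it too (camera adjusted p = 0.117). Missing it therefore does not tell a list that changed from one that did not. Calls adjusted over a list alone used the same p-values with adjustment within the list. The design, the lists and the rule for named genes were fixed before the data were examined. The rule took up to 10 rises and 10 falls per contrast, the largest on the log2 scale among loci past the threshold whose compared arrays did not overlap and that had a symbol, up to 4 members per list (those past the threshold, or else the 2 with the largest change), and GEM, the ABA receptors, the clade A phosphatases and the epidermal fate genes at any value.

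The labels number the replicates 1 and 2 in every group. Deviations of the replicates from their group means correlated across loci in all 15 pairs of groups, from 0.44 to 0.88 (median 0.71). The first principal component separated the replicate numbers and held 43.8% of the variance, and the second separated the treatments with 39.1%. The replicate number took 39.2% of the variance, treatment 38.5% and genotype 3.56%. The numbers were therefore taken to pair the samples, and values with the replicate number as a block are given where they change a call or move a count by more than 1.5 times. All 12 arrays were used.

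The alternatives were the replicate block, a fit of only the contrast's groups, a variance trend, array weights, leaving out the dimmest 30% of loci, a shift of the arrays to 1 median, quantile normalization again, every transcript feature, the whole-series table, a 2-fold minimum and each array left out in turn. Genotype contrasts averaged over treatments, list medians within each replicate set, exact tests of GEM and each array left out with the replicate block kept were added after seeing the data. The fit and the list test were tested on simulated data in which 200 loci were changed by known amounts. The list test with the preset correlation found the list that was shifted by 1 on the log2 scale, the aquaporins, and also called 1 of the lists that were not shifted. Data were read with the R packages jsonlite 2.0.0 and data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.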

Results

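Transcript levels were measured in whole seedlings of Arabidopsis thaliana, accession Col-0, at 10 days of age. The seedlings were wild type, a T-DNA insertion line named gem1, or a line that overexpresses GEM from the viral 35S promoter. GEM (GL2-EXPRESSION MODULATOR) is a GRAM domain protein known for its part in the choice of epidermal cell fate in the root. Each genotype was measured without treatment and after 2 hours with 100 uM abscisic acid (ABA), the hormone of drought and seed dormancy, with 2 biological replicates in each of the 6 groups. The labels name no mock-treated group, so handling and elapsed time cannot be told apart from ABA in what is called its response. The 12 one-colour arrays carried 37118 transcripts each, and their medians lay between 12.16 and 12.22 on the log2 scale. Between 11.4% and 11.8% of the transcripts on an array had a value over 15, near the highest value of 15.95, so that a rise from such a level had little room. No background or saturation flags were in the values used here, and the number of arrays limits the precision.

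GEM (AT2G22475, chromosome 2, 9541401 to 9545010 in the coordinates of the array annotation, whose build is not given in the sources used here) was read by a pair of transcript features. Feature 1 stood at 15.80 ± 0.02 without ABA and 15.73 ± 0.01 with ABA in the overexpressor, against 14.30 ± 0.25 and 14.39 ± 0.02 in wild type (log2, mean ± SD, n = 2). The arrays labelled gem1 gave 14.50 ± 0.16 and 14.52 ± 0.11 for the same feature, so that GEM was not lower on them than in wild type. Feature 2 stood at 9.52 ± 0.19 and 9.43 ± 0.15 in wild type and at 11.39 ± 0.32 and 11.43 ± 0.14 on the arrays labelled gem1. In the overexpressor feature 2 was 11.36 and 11.98 in replicate 1, without and with ABA, and 9.56 and 9.38 in replicate 2. The overexpressor exceeded wild type in feature 1 by 1.5 without ABA (SE 0.14, 2.82-fold) and by 1.34 with ABA (SE 0.14, 2.54-fold). These are read as lower bounds, since the overexpressor values lie near 15.95, the highest on any array, where values are compressed. The limma adjusted p over all transcripts was 0.234 and 0.516, and 0.0769 and 0.166 with the replicate number as a block. Adjusted over the 18 GEM tests alone it was 0.000114 and 0.000125. Feature 2 differed between the arrays labelled gem1 and wild type by 1.87 without ABA and 2.00 with ABA (SE 0.83 for both). Neither difference passed over all transcripts, and the limma adjusted p over the 18 tests was 0.248 for both. In exact tests added after the data were seen, 4 overexpressor arrays over both treatments against 4 of wild type gave 1.42 for feature 1 (two-sided exact permutation p = 0.0286, the smallest that 70 splits allow, 0.0572 after adjustment over 4 tests). The arrays labelled gem1 differed by 0.16 in feature 1 (exact permutation p = 0.171, adjusted 0.228) and by 1.94 in feature 2 (exact permutation p = 0.0286, adjusted 0.0572). Those splits treat treatments and replicate numbers as exchangeable. With swaps only within treatment and replicate number, the exact permutation p was 0.125 for each of these 3 differences, the smallest that 16 swaps allow. The place of the insertion relative to the probes is not given in the sources used here, so a transcript upstream or downstream of it does not check the label.

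**Figure D1:**
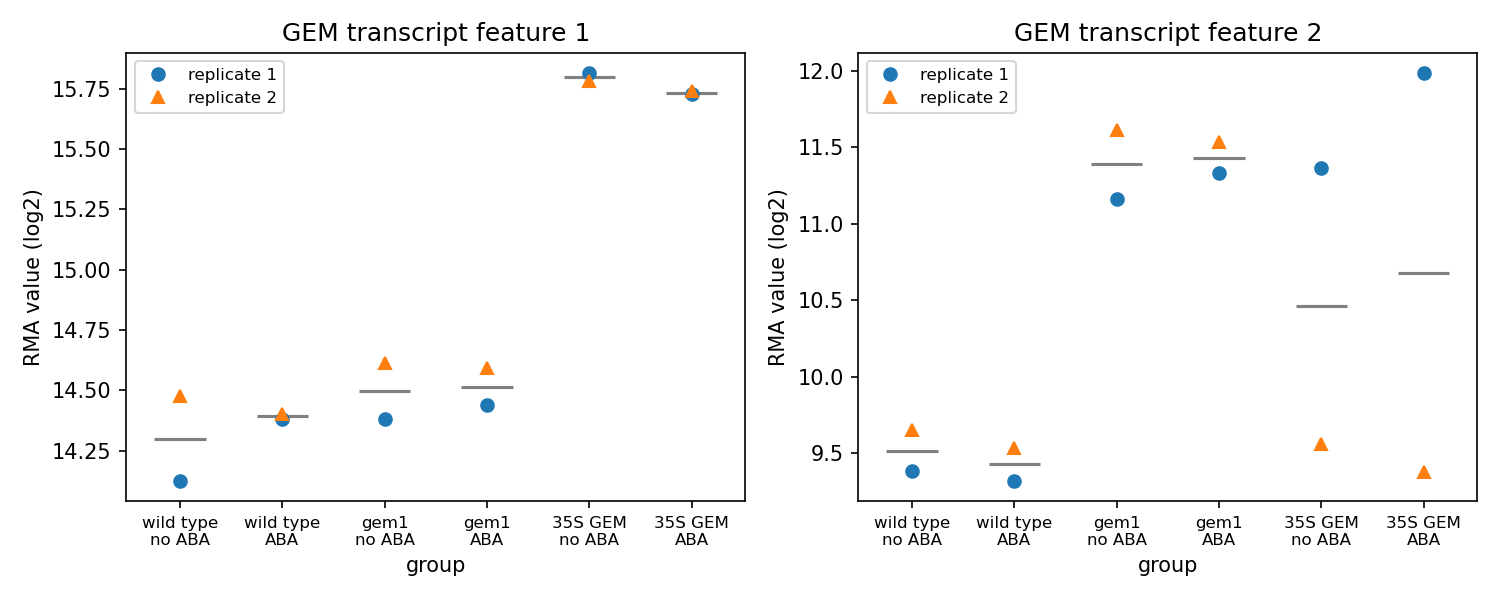
RMA values (log2) of both GEM transcript features on each of the 12 arrays, by genotype and treatment (circles replicate 1, triangles replicate 2, grey lines group means, n = 2). In feature 1 the 4 overexpressor arrays lie at 15.73 or above and all others at 14.61 or below, and in feature 2 the arrays labelled gem1 lie at 11.16 or above.

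ABA raised known ABA-responsive genes in wild type within 2 hours. HAI3, a clade A protein phosphatase that restrains ABA signalling, rose 33.5-fold (log2 5.07, SE 0.53, n = 2, adjusted p = 0.00622). SOM, a zinc finger repressor of seed germination, rose by 4.79 (SE 0.42, adjusted p = 0.00367), and SAG29, the sugar transporter SWEET15, by 4.79 (SE 0.78, adjusted p = 0.034). The heat stress factor HSFA6A rose by 4.47, MYB121 by 4.17, DIP2 by 4.1, the kinase MAPKKK18 by 4.07, the cold- and ABA-induced gene KIN1 by 4.07, the malic enzyme NADP-ME1 by 3.86 and HVA22B by 3.79. KIN1 lies beside its near-identical copy KIN2, so its share of the signal is uncertain. RBOHB, an NADPH oxidase, fell by 2.79 (SE 0.27, adjusted p = 0.00499), and NAS1, a nicotianamine synthase of metal transport, fell by 2.77 (SE 0.35, adjusted p = 0.0142). CYP735A2, which makes trans-zeatin cytokinins, changed by -2.72, the ERF factor gene tny by -2.60, CYP702A5 by -2.32, the expansin EXPA14 by -2.16, the zinc finger gene MGP by -2.08, JAZ4 by -2.01, the cytokinin transporter ABCG14 by -2.01 and GIK by -1.99. HAI3 lies on chromosome 2 (12608702 to 12610167) and RBOHB on chromosome 1 (2932739 to 2936586) in the array annotation.

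With limma, 346 loci were higher and 100 lower after ABA in wild type (446 of 32627, 77.6% higher). With the replicate number as a block the counts were 1086 and 877 (1963, 55.3% higher), and all 446 were among them. At an unadjusted p under 0.05 there were 3905 loci by limma (7042 with the block), with 1630 expected by chance. That number is no strict mark for the fit without the block, whose spread also holds the difference between the replicate sets. No locus passed when only the 4 arrays of the contrast were fitted. The count was 223 without untreated wild-type replicate 1, 103 without untreated replicate 2, 87 and 41 without ABA-treated wild-type replicate 1 and 2, 210 without either ABA-treated gem1 array and 288 without either ABA-treated overexpressor array. Of the 20 genes named above, 11, 14, 13 and 19 missed the threshold without untreated wild-type replicate 1, untreated replicate 2, ABA-treated replicate 1 and ABA-treated replicate 2, and all 20 kept their sign. MYB121 alone stayed past it whichever of the 12 arrays was left out, while SAG29, NADP-ME1, CYP735A2 and GIK passed in 2 of the 12 fits. Of the 30 list members past the threshold, 15, 24, 25 and 27 missed it without the same arrays, 15 without either ABA-treated gem1 array, and all 30 kept their sign. CYP707A1, AT3G15670 and ECP63 stayed past it whichever of the 12 was left out. These fits have no block, so that an array left out brings the difference between the replicate sets into its group. With the block kept, added after the data were seen, the count ranged from 371 without ABA-treated wild-type replicate 2 to 2506 without untreated overexpressor replicate 1.

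Among the lists fixed beforehand, the 28 ABA-induced marker genes had a median change of 2.3 in wild type, and all 28 were higher. Over all loci 6 of the 28 rose, 17 when adjusted over the list alone and 14 with the replicate block. KIN1, NAC3 (2.96, SE 0.32), LTI65 (2.9, SE 0.34) and HB-12 (2.81, SE 0.40) led them, LTI65 being also known as RD29B. The list passed camera with a preset correlation and had adjusted p = 0.117 with an estimated correlation. Of the 28 markers, 8 had untreated values over 15 and changes of at most 0.48, while the other 20 had a median of 2.85. The 9 clade A PP2C phosphatases, the coreceptors that restrain ABA signalling, had a median of 1.03 (adjusted p = 0.117 with an estimated correlation). HAI3 rose over all loci, 5 of 9 rose adjusted over the list alone, and 5 with the block. HAI1 gave 3.86 (SE 1.64), HAI2 2.91 (SE 0.72), ABI2 2.68 (SE 0.57) and ABI1 1.03 (SE 0.24), none of them past the threshold over all loci. The 20 seed maturation genes had a median of 1.80 (adjusted p = 0.117 with an estimated correlation), and 6 rose over all loci, 7 adjusted over the list alone. The late embryogenesis abundant genes AT3G17520 (5.15, SE 0.57), LEA18 (3.5, SE 0.34), GEA6 (3.3, SE 0.50) and ECP63 (3.09, SE 0.18) led them. The seed maturation median was 0.37 without ABA-treated wild-type replicate 2 and 3.13 without ABA-treated wild-type replicate 1.

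Single genes in other parts of the ABA pathway rose after treatment in wild type. CYP707A1, an ABA 8'-hydroxylase that breaks the hormone down, rose by 3.02 (SE 0.15, adjusted p = 0.000637), the single locus of 16 in the ABA synthesis and breakdown list to pass over all loci, with 4 adjusted over the list alone, 3 with the block and a list median of 0.29 (adjusted p = 0.117 with an estimated correlation). ABI5 rose by 2.51 (SE 0.38), ABF2 by 1.18 (SE 0.20) and ABF4 by 0.83 (SE 0.13), which made 3 of 10 ABA transcription factors, with 5 adjusted over the list alone (median 0.25, adjusted p = 0.103 with an estimated correlation). SNRK2.7 rose by 2.75 (SE 0.34) and the kinase OST1 of guard cell ABA signalling by 0.98 (SE 0.10), 2 of 10 SnRK2 kinases, with 3 adjusted over the list alone (median 0.18, adjusted p = 0.103 with an estimated correlation). CBF1 rose by 2.02 (SE 0.33) and DREB2A by 1.43 (SE 0.26), 2 of 6 cold and DREB factors, with 3 adjusted over the list alone (the CBF genes being near-identical neighbours, so that the share of each is uncertain; median 1.53, adjusted p = 0.117 with an estimated correlation). Of the 14 ABA receptors none passed over all loci, while 2 were higher and 6 lower adjusted over the list alone (median -0.35). PYL6 gave -3.99 (SE 0.96), PYL5 -2.27 (SE 0.84) and PYL4 -2.19 (SE 0.54), with limma adjusted p = 0.114, 0.32 and 0.123, 1 receptor being higher and 1 lower with the block, and PYL1 gave -0.73 with adjusted p = 0.0833, or 0.00867 with the block.

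Among expansins and root genes few single loci passed in ABA-treated wild type. The 13 alpha-expansins had a median of -0.81 (adjusted p = 0.103 with an estimated correlation), and EXPA14 and EXPA1 (-1.55, SE 0.26) fell over all loci. Adjusted over the list alone 7 were lower and 1 higher, and with the block 4 were lower and 1 higher. The 25 root hair growth genes had a median of -0.57 (adjusted p = 0.368 with an estimated correlation). None of them passed over all loci, 2 were lower adjusted over the list alone and 3 with the block, and RHS13 gave -1.86 (SE 0.37, adjusted p = 0.0633). The 17 root tissue markers had a median of -0.46 (adjusted p = 0.368 with an estimated correlation). CASP5, a Casparian strip protein, rose by 0.92 (SE 0.11), against the direction of its list, with 1 higher and 1 lower adjusted over the list alone, and 1 higher and 5 lower with the block. Without untreated wild-type replicate 1 the preset call of this list ended (median -0.39, adjusted p = 0.186). The rapid stress and touch genes CML37 (0.96, SE 0.16) and RHL41 (0.88, SE 0.15) rose, 2 of 13 over all loci and over the list alone (median 0.25, adjusted p = 0.415 with an estimated correlation). That list gave -0.08 (adjusted p = 0.344) without untreated wild-type replicate 1 and -0.02 (adjusted p = 0.232) without ABA-treated replicate 1. The 18 aquaporins had a median of 0.10 (adjusted p = 0.368 with an estimated correlation) with 0 past over all loci by limma, 1 adjusted over the list alone and 1 higher with the block. Of these, 12 had untreated values over 15 and little room to rise. Their preset call ended without untreated wild-type replicate 1 or ABA-treated replicate 2. With the block kept and an array left out, the medians lay between -0.65 and -0.35 (root tissue), -0.11 and 0.79 (rapid stress) and 0.06 and 0.14 (aquaporins).

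Regulators of root hair and trichome fate, which GEM is known to affect, held 1 gene that passed. CPL3, a single-repeat MYB that represses trichomes, rose by 1.74 (SE 0.30, adjusted p = 0.0424) in wild type, by 1.80 (SE 0.30, adjusted p = 0.0371) on the arrays labelled gem1 and by 1.67 (SE 0.30, adjusted p = 0.0476) in the overexpressor. MYB66, also known as WEREWOLF, gave -1.37 (SE 0.29), -1.06 (SE 0.29) and -1.34 (SE 0.29), with adjusted p = 0.0821, 0.168 and 0.0815, and with the block 0.0146, 0.0337 and 0.015. GL2, the gene after which GEM is named, gave -0.20 (SE 0.26) in wild type. CPL3 kept its call without 2, 2 and 0 of the 12 arrays left out in turn in the 3 genotypes. The list of 18 had medians of -0.22, -0.27 and -0.31 and was not called, except in the overexpressor with the block (adjusted p = 0.0244, and 0.433 with an estimated correlation). In wild type 1 member was higher and 3 lower adjusted over the list alone. Lists that were not called in wild type had medians of 0.31 (heat shock proteins), 0.12 (circadian clock), 0.01 (reference genes), 0.00 (jasmonate response), -0.01 (light harvesting and Rubisco), -0.03 (salicylate defence), -0.05 (auxin early response), -0.07 (cell cycle), -0.16 (flavonoid and anthocyanin synthesis), -0.21 (stomatal lineage), -0.25 (gibberellin pathway) and -0.41 (GEM-like family). Of the 19 light harvesting and Rubisco genes 15 had untreated values over 15, with little room to rise. The clock list was called with the block (adjusted p = 0.00146, and 0.182 with an estimated correlation), with BOA at 1.61 (SE 1.58) and CCA1 at 1.46 (SE 1.07). Single members that rose in uncalled lists were WES1 (1.06), GA2OX6 (2.25), which inactivates gibberellins, and JAZ1 (0.75), with 1 jasmonate, 2 gibberellin and 1 auxin gene higher adjusted over the list alone. By the same adjustment 1 GEM-like gene was higher, and 1 gibberellin, 1 auxin and 1 stomatal gene were lower. With the block 4 jasmonate genes, 3 clock genes and 1 GEM-like gene were higher, 3 gibberellin genes were higher and 2 lower, and 1 auxin gene was higher and 1 lower. For auxin and light harvesting the median and the camera test differed in sign, and for the GEM-like family the median was negative and the mean 0.02.

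**Figure D2:**
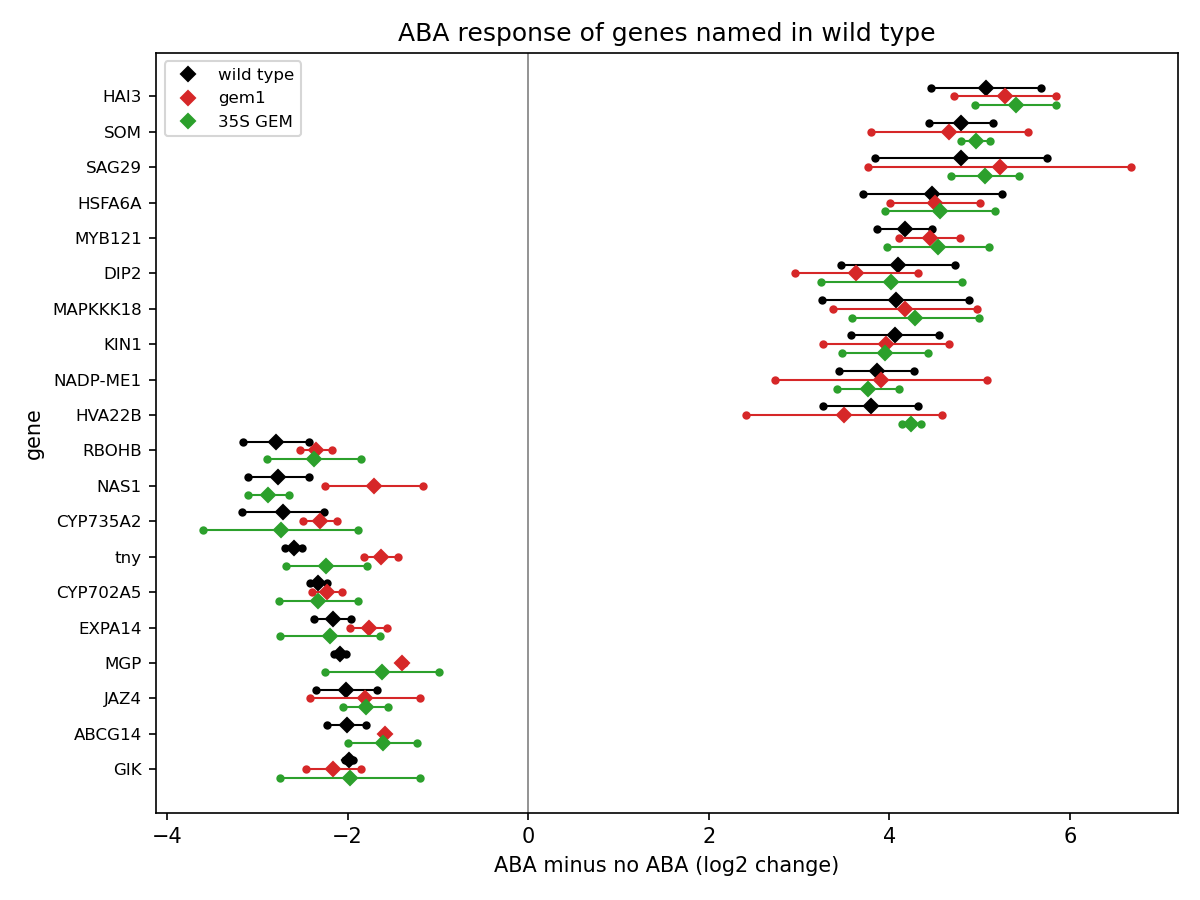
Change after ABA (log2) of the 20 genes named in wild type, in each genotype (small joined points the replicate 1 and replicate 2 differences, diamonds their mean). HAI3 lies at 5.07, 5.28 and 5.40 in wild type, gem1 and the overexpressor, and every mean has the same sign in the 3 genotypes.

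On the arrays labelled gem1, NAC019, a stress-induced NAC factor, rose by 5.49 (SE 0.80, adjusted p = 0.0219), HAI3 by 5.28 (SE 0.53, adjusted p = 0.00574), SAG29 by 5.22 and SOM by 4.66. HSFA6A (4.50), MYB121 (4.44), EDL3 (4.18), MAPKKK18 (4.17), ChlAKR (4.0) and KIN1 (3.96) followed. RBOHB fell by 2.35 (SE 0.27), CYP702A5 fell by 2.23, GIK fell by 2.16, CYP716A2 fell by 2.12 and EXPA1 fell by 2.07, with JAZ4 (-1.80), EXPA14 (-1.77), the ammonium transporter AMT1;3 (-1.71), tny (-1.63) and the tyrosine decarboxylase TYRDC (-1.45) after them. The ABA-induced markers had a median of 2.4 with 10 of 28 past over all loci, 18 adjusted over the list alone and 15 with the block (adjusted p = 0.0983 with an estimated correlation). The clade A phosphatases had a median of 1.03 with 1 of 9 past, 7 adjusted over the list alone and 4 with the block (adjusted p = 0.0983 with an estimated correlation). CYP707A1 rose by 3.11 and CYP707A4 by 2.67, 2 of 16 ABA metabolism genes, with 5 adjusted over the list alone and 4 with the block (adjusted p = 0.0874 with an estimated correlation). In the other ABA groups of gem1, ABI5 (2.61, SE 0.38), ABF2 (1.2) and ABF4 (0.77) rose, 3 of 10 transcription factors and 4 adjusted over the list alone (adjusted p = 0.0776 with an estimated correlation). SNRK2.7 (2.49) and OST1 (0.81) rose, 2 of 10 kinases and 3 adjusted over the list alone (adjusted p = 0.101 with an estimated correlation), as did CBF1 (1.99) and DREB2A (1.46), 2 of 6 and 4 adjusted over the list alone (adjusted p = 0.0874 with an estimated correlation). AT3G17520 (4.72), LEA18 (3.1), ECP63 (2.91) and AT3G15670 (2.85) led 5 of 20 seed maturation genes that rose, with 7 adjusted over the list alone and a median of 0.14 (adjusted p = 0.279 with an estimated correlation). That median was -0.28 without ABA-treated gem1 replicate 2 and 1.41 without ABA-treated gem1 replicate 1. EXPA1, EXPA14 and EXPA5 (-1.03) made 3 of 13 expansins that fell, with 7 adjusted over the list alone and 5 with the block (adjusted p = 0.0776 with an estimated correlation). With limma 386 loci were higher and 89 lower (475, 81.3% higher), and with the replicate block 1213 and 598 (1811, 67% higher), including all 475. The count was 0 with only the 4 arrays of the contrast, 3407 at an unadjusted p under 0.05, 116 without untreated gem1 replicate 2, 66 and 40 without ABA-treated gem1 replicate 1 and 2, and 256 without either ABA-treated wild-type array. Of the 20 named genes 8, 15, 16 and 19 missed the threshold without untreated gem1 replicate 1, untreated replicate 2, ABA-treated replicate 1 and ABA-treated replicate 2. EDL3 and ChlAKR passed in 3 and JAZ4 in 2 of the 12 fits with an array left out. With the block kept the count ranged from 348 without ABA-treated gem1 replicate 2 to 1730 without untreated overexpressor replicate 1. Of the 36 list members past the threshold without the block, 13, 25, 33 and 33 missed it without the same arrays, and all 36 kept their sign.

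Further gene groups were called on the arrays labelled gem1 with a preset correlation. Jasmonate genes had a median of 0.28, with 20 of 21 values above 0, with JAZ1 (1.07, SE 0.11) past the threshold, 1 adjusted over the list alone and 4 with the block (adjusted p = 0.47 with an estimated correlation). Root hair growth genes had a median of -0.56, with 0 of 25 past over all loci by limma, 7 lower adjusted over the list alone and 3 with the block (adjusted p = 0.374 with an estimated correlation). CASP5 (0.84) rose and CASP2 (-1.06) fell among 17 root tissue markers, with 1 higher and 4 lower adjusted over the list alone and with the block (median -0.35, adjusted p = 0.47 with an estimated correlation). CML37 rose by 1.34 among the 13 rapid stress genes, 1 over all loci and 2 adjusted over the list alone (median 0.66, adjusted p = 0.47 with an estimated correlation). Flavonoid genes had a median of 0.30 with none of 16 past over all loci or over the list alone, and TT8 at 1.96 (SE 0.47, adjusted p = 0.111, with the block 0.0116), and heat shock genes a median of 0.45 with none of 12 past (adjusted p = 0.565 and 0.117 with an estimated correlation). The rapid stress call (0.08) and the root tissue call (0.01) ended without untreated gem1 replicate 1, the latter also without ABA-treated replicate 2 (adjusted p = 0.147), and the jasmonate call without ABA-treated replicate 1 (0.01). The flavonoid median turned to -0.50 without untreated gem1 replicate 2 and was 0.01 without ABA-treated replicate 1. The flavonoid call also ended without the dimmest 30% of loci (adjusted p = 0.335), as did the root tissue call here (0.0912) and in wild type (0.0587). The fits above with an array left out have no block. With it kept, the jasmonate median lay between 0.25 and 0.41 and the flavonoid median between 0.06 and 0.60. The rapid stress median then lay between 0.20 and 0.77 and the root tissue median between -0.51 and -0.06. Over all 6 groups, replicate 2 was lower than replicate 1 for 14 of the 16 flavonoid genes (median -1.02) and 15 of the 21 jasmonate genes (median -0.36) past the threshold, where 15350 of all 32627 loci passed in either direction. With the block 1 ABA receptor was higher and 4 lower in gem1, 2 auxin genes were higher and 1 lower, 2 rapid stress genes, 2 clock genes, 1 GEM-like gene, 1 cell cycle gene and 1 aquaporin were higher, and 1 light harvesting gene was lower.

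In the GEM overexpressor HAI3 rose by 5.40 (SE 0.53, adjusted p = 0.00567), SAG29 by 5.06, SOM by 4.95, NAC019 by 4.78, HSFA6A by 4.56, MYB121 by 4.54, MAPKKK18 by 4.28, HVA22B by 4.24, DIP2 by 4.02 and the ERF factor RAP2.6 by 4.0. NAS1 fell by 2.88, CYP735A2 fell by 2.74, the cell wall enzyme XTH31 fell by 2.74 and RBOHB fell by 2.37 (SE 0.27), before CYP702A5 (-2.32), tny (-2.23), EXPA14 (-2.20), CYP716A2 (-2.08), EXPA1 (-2.08) and GIK (-1.98). PYL1, an ABA receptor, fell by 0.85 (SE 0.16, adjusted p = 0.0479), and kept this call without 2 of the 12 arrays left out in turn, while PYL6 gave -4.14 (SE 0.96, adjusted p = 0.0984). With the block 1 receptor was higher and 4 were lower. CYP707A1 (3.12) and CYP707A4 (2.35) rose, 2 of 16 ABA metabolism genes, with 6 adjusted over the list alone and 4 with the block (adjusted p = 0.0942 with an estimated correlation). The ABA-induced markers had a median of 2.37 with 9 of 28 past over all loci, 19 adjusted over the list alone and 16 with the block (adjusted p = 0.105 with an estimated correlation). The clade A phosphatases had a median of 1.34 with 1 of 9 past, 8 adjusted over the list alone and 5 with the block (adjusted p = 0.105 with an estimated correlation). EXPA14, EXPA1 and EXPA5 (-0.81) were the 3 expansins that fell, with 7 adjusted over the list alone and 5 with the block (adjusted p = 0.0942 with an estimated correlation). With limma 387 loci were higher and 119 lower (506, 76.5% higher), and with the block 1142 and 768 (1910, 59.8% higher), including all 506. The count was 0 with only the 4 arrays of the contrast, 3847 at an unadjusted p under 0.05, 200 and 94 without untreated overexpressor replicate 1 and 2, 172 and 86 without ABA-treated overexpressor replicate 1 and 2, 266 without either ABA-treated wild-type array and 241 without either ABA-treated gem1 array. Of the 20 named genes 10, 14, 9 and 14 missed the threshold without untreated overexpressor replicate 1, untreated replicate 2, ABA-treated replicate 1 and ABA-treated replicate 2. XTH31 passed in 0 of the 12 limma fits with an array left out (highest adjusted p = 0.287), GIK in 1, NAC019 in 2 and CYP735A2 in 3. With the block kept the count ranged from 437 without ABA-treated overexpressor replicate 2 to 1928 without untreated overexpressor replicate 1. Of the 38 list members past the threshold without the block, 24, 31, 22 and 30 missed it without the same arrays, and all 38 kept their sign.

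In the other gene groups of the overexpressor, ABI5 (2.48), ABF4 (0.86) and ABF2 (1.19) rose, 3 of 10 transcription factors and 4 adjusted over the list alone (adjusted p = 0.0942 with an estimated correlation). SNRK2.7 (2.64) and OST1 (0.97) rose, 2 of 10 kinases over all loci and over the list alone (adjusted p = 0.134 with an estimated correlation), a preset call that ended without ABA-treated overexpressor replicate 1 (0.0612). DREB2A (1.64) and CBF1 (1.85) rose, 2 of 6 and 4 adjusted over the list alone (adjusted p = 0.105 with an estimated correlation). AT3G17520 (5.10), AT3G15670 (3.29), GEA6 (3.19) and ECP63 (3.15) led 6 of 20 seed maturation genes that rose, 7 adjusted over the list alone (median 0.39, adjusted p = 0.194 with an estimated correlation), with a median of 0.05 without ABA-treated overexpressor replicate 2 and 1.2 without ABA-treated overexpressor replicate 1. JAZ1 (0.72) rose among 21 jasmonate genes, 1 over the list alone too (median 0.17, adjusted p = 0.688 with an estimated correlation). Root hair growth genes had a median of -0.52, with 0 of 25 past over all loci by limma, 11 lower adjusted over the list alone and 3 with the block (adjusted p = 0.3 with an estimated correlation). CASP5 (1.00) rose and CASP2 (-1.16) fell, with 1 higher and 2 lower root tissue markers adjusted over the list alone and 4 lower with the block (median -0.47, adjusted p = 0.3 with an estimated correlation). Stomatal genes had a median of -0.25, with 0 of 11 past over all loci by limma and 1 lower adjusted over the list alone and with the block, EPF2 at -1.08 being the largest (adjusted p = 0.194 with an estimated correlation). Flavonoid (0.22) and heat shock (0.42) genes had none past over all loci or over the list alone (adjusted p = 0.704 and 0.276 with an estimated correlation), while with the block 2 flavonoid genes were higher. Without untreated overexpressor replicate 2 the jasmonate (-0.10) and flavonoid (-0.26) calls ended, and without ABA-treated replicate 1 the jasmonate (0.11), flavonoid (-0.07) and heat shock (0.33) calls. The heat shock call ended without untreated replicate 1 (0.08) and the root tissue call without ABA-treated replicate 2 (-0.33). The flavonoid call also ended without the dimmest 30% of loci (adjusted p = 0.345) and with a second quantile normalization (0.0634). The fits above with an array left out have no block. With it kept, the jasmonate median lay between 0.01 and 0.33 and the flavonoid median between 0.15 and 0.54. The heat shock median then lay between 0.24 and 0.61 and the root tissue median between -0.50 and -0.35. The rapid stress list was not called, with a median of -0.04 and a mean of 0.09, while CML37 (1.34) and RHL41 (0.84) rose. The clock list was called with the block alone, as in gem1 (adjusted p = 0.011 and 0.0394, and 0.29 and 0.315 with an estimated correlation). With the block 4 clock genes, 3 gibberellin genes and 1 GEM-like gene were higher, 1 auxin gene was higher and 1 lower, and 1 epidermal fate gene was higher and 2 lower.

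**Figure D3:**
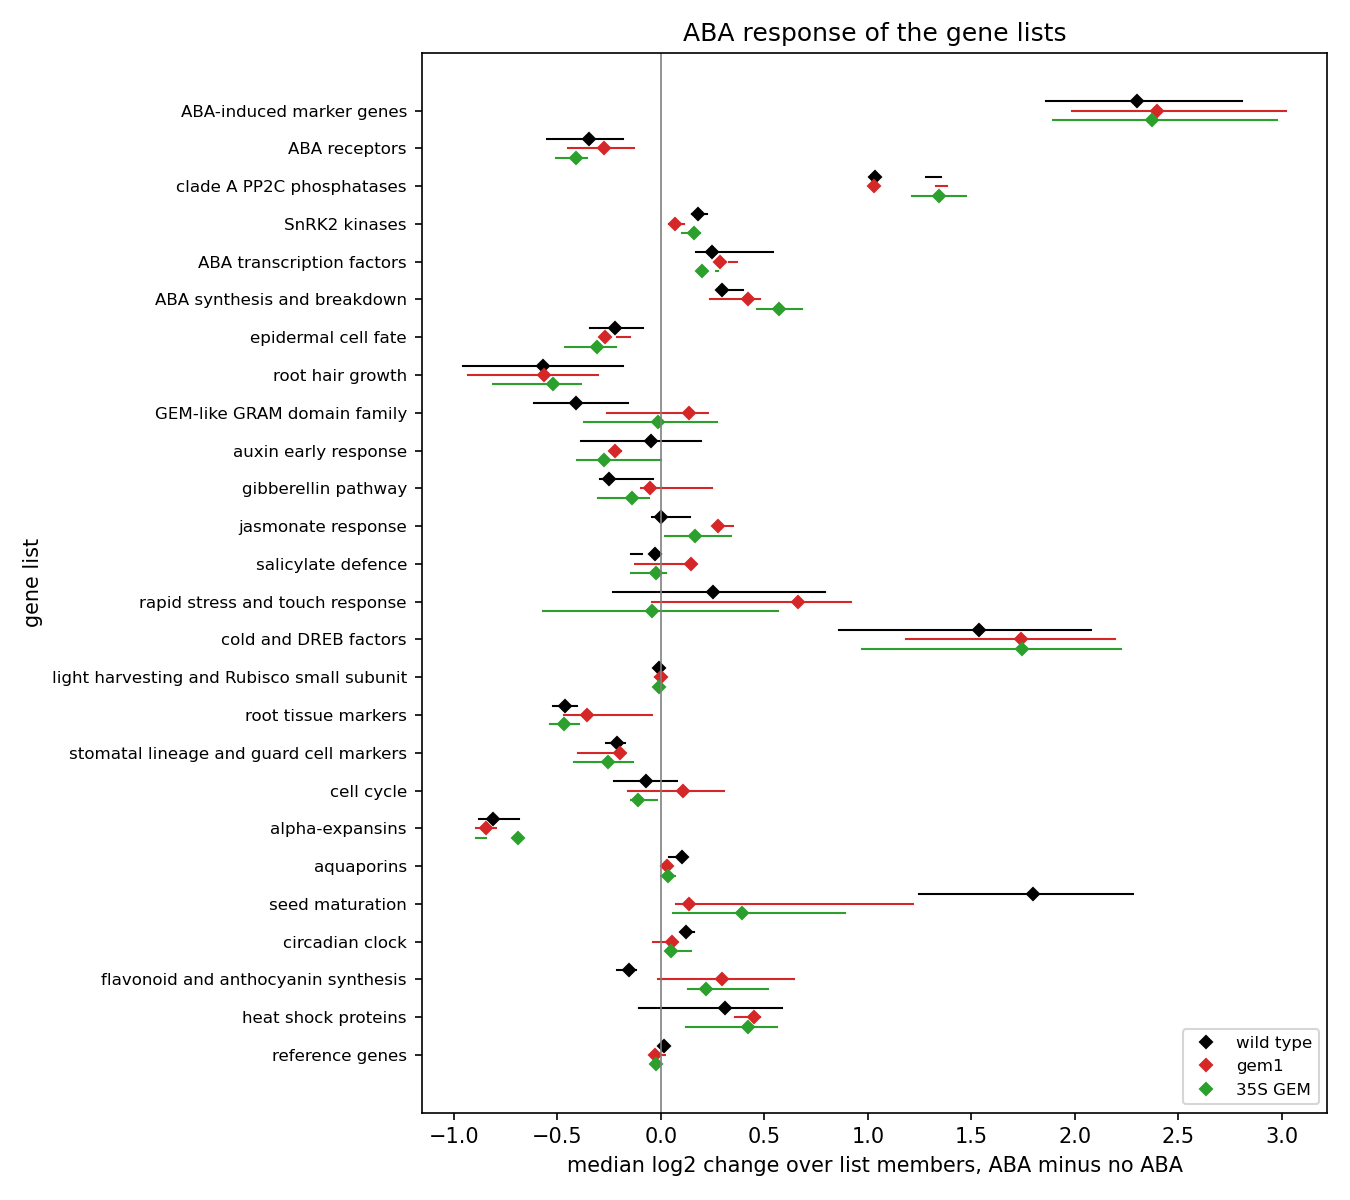
Median change after ABA (log2) over the members of each of the 26 gene lists, by genotype (diamonds medians over group means, lines joining the medians of the 2 replicate sets, which can both lie on 1 side of the diamond). The ABA-induced markers lie at 2.3, 2.4 and 2.37 in wild type, gem1 and the overexpressor, and the alpha-expansins at -0.81, -0.84 and -0.69.

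The ABA response was largely shared between the 3 genotypes. The higher loci held 277 called in all 3 genotypes out of 481 called in at least 1, and the lower loci 54 of 156, and no locus was called in opposite directions. With the block 834 and 384 were called in all 3. Wild type and gem1 shared 286 higher and 60 lower loci, against 4.09 and 0.273 expected of independent lists, wild type and the overexpressor shared 301 and 71 (4.1 and 0.365), and gem1 and the overexpressor 328 and 75 (4.58 and 0.325). The means of these contrasts come from separate arrays, but 1 fit of all 12 gives each locus the same spread in all 3. Loci of low spread are thus favoured in every list, and the numbers expected of independent lists are not a strict mark. Across 32627 loci, which are not independent replicates, the changes correlated with r = 0.83, 0.89 and 0.89. The mean value of the ABA-induced markers went from 13.08 ± 0.71 to 15.24 ± 0.00 in wild type, from 12.91 ± 0.80 to 15.21 ± 0.03 on the arrays labelled gem1 and from 12.89 ± 0.83 to 15.24 ± 0.01 in the overexpressor (mean ± SD, n = 2). The treated means lie near the highest value of 15.95, and 8 of the 28 markers were over 15 before treatment, so their equal level after ABA says little about the size of the response. Untreated, the markers were higher in replicate 1 than in replicate 2 in every genotype (13.58 and 12.58 in wild type, 13.48 and 12.34 on the arrays labelled gem1, 13.48 and 12.30 in the overexpressor). The response of gem1 differed from that of wild type by 0.14 (95% interval -1.78 to 2.06, with the block -1.45 to 1.73) and that of the overexpressor by 0.20 (-1.72 to 2.12, with the block -1.39 to 1.79). The replicates differed far less after ABA, so the block, with 1 shift for all groups, leaves part of the untreated difference in the spread. That widens these intervals.

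The size of the response was compared at loci called in the third genotype. Over the 387 loci higher in the overexpressor the median change was 1.47 in wild type and 1.55 in gem1, a difference of 0.08 (0.11 and 0.01 in replicate sets 1 and 2). Over its 119 lower loci the medians were -1.19 and -1.12 (differences of 0.07 and 0.08 in the sets). That difference turned to -0.0448 with a second quantile normalization and to -0.0009 without the dimmest 30% of loci, and lay between 0.0327 without ABA-treated gem1 replicate 2 and 0.4509 without untreated overexpressor replicate 2. Over the 386 loci higher in gem1 they were 1.49 in wild type and 1.57 in the overexpressor, with differences of 0.22 and -0.05 in the replicate sets, and over the 89 lower loci -1.27 and -1.24, with differences of 0.26 and -0.19. Over the 346 loci higher in wild type they were 1.53 in gem1 and 1.56 in the overexpressor, and over the 100 lower loci -1.19 and -1.25, with set differences of 0.10 and -0.05 at the higher and 0.19 and -0.29 at the lower loci. In these last 4 comparisons the sets differed in sign. The difference between gem1 and wild type at the higher loci turned to -0.15 without untreated wild-type replicate 1 and reached 0.29 without untreated gem1 replicate 1.

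No locus passed between the arrays labelled gem1 and wild type without ABA (limma, 161 loci at an unadjusted p under 0.05 against 1630 expected by chance, 0 and 636 with the replicate block). Counts this far below the expected number, here and in the other genotype contrasts, show p-values that cannot be read against it. Without the block the spread also holds the difference between the replicate sets. The lack of calls therefore does not show that the genotypes are alike. The 21 jasmonate response genes had a median of -0.25 in gem1 and 20 of them were lower, with JAZ5 at -0.91 (SE 1.17) and VSP2 at -0.84 (SE 1.00), and the preset camera call had adjusted p = 0.903 with an estimated correlation. The 25 cell cycle genes had a median of -0.11 (0.05 and -0.23 in the replicate sets), with CYCA1;1 at -0.32 (SE 0.24) and adjusted p = 0.903 with an estimated correlation. With the block kept and an array left out, the jasmonate median lay between -0.39 and -0.10 and the cell cycle median between -0.26 and 0.06. Without the block the jasmonate call ended without untreated wild-type replicate 1 (-0.01) or untreated gem1 replicate 2 (-0.04), and the cell cycle median was 0.13 without untreated gem1 replicate 2 and -0.01 without untreated wild-type replicate 1. Without untreated wild-type replicate 2 a single locus passed. With the block 4 lists were called in place of 2, salicylate defence (median -0.04) and the circadian clock (0.11) being added (adjusted p = 0.958 and 0.759 with an estimated correlation). Over all 6 groups 15 of the 21 jasmonate genes were lower in replicate 2 than in replicate 1 past the threshold.

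No locus passed between the overexpressor and wild type without ABA either (limma, 166 loci at an unadjusted p under 0.05, 0 and 632 with the block, 1630 expected by chance). The 23 early auxin genes had a median of 0.37 and 22 of them were higher, with SAUR22 at 0.81 (SE 0.51) and the SAUR gene AT2G18010 at 0.74 (SE 0.75), and adjusted p = 0.906 with an estimated correlation. All 16 flavonoid genes were lower (median -0.40), with DFR at -0.93 (SE 1.45) and PAP1 at -0.83 (SE 0.97), and 12 of 13 rapid stress genes were higher (median 0.40), with CML38 at 0.58 (SE 0.63) (adjusted p = 0.906 with an estimated correlation for both). The 25 root hair growth genes had a median of 0.09 (adjusted p = 0.906 with an estimated correlation), and this call ended with the block (adjusted p = 0.215), without untreated wild-type replicate 2 (-0.07), without untreated overexpressor replicate 2 (0.00), and without either untreated gem1 array (adjusted p = 0.0596) or either ABA-treated overexpressor array (0.0544). SAUR22 lies among near-identical SAUR copies, so its single value is uncertain. With the block the jasmonate list was called too (median -0.14, adjusted p = 0.847 with an estimated correlation). The root hair call also ended with array weights (adjusted p = 0.0953), without the dimmest 30% of loci (0.14) and with a second quantile normalization (0.0754). Over all 6 groups, replicate 2 was lower than replicate 1 for 14 of the 16 flavonoid genes past the threshold and higher for 14 of the 23 auxin genes. With the block kept and an array left out, the auxin median lay between 0.24 and 0.51 and the flavonoid median between -0.49 and -0.27. The rapid stress median then lay between 0.04 and 0.82 and the root hair median between -0.155 and 0.323. Without the block the auxin median was 0.17 without untreated wild-type replicate 1 and 0.02 without untreated overexpressor replicate 2, the flavonoid median 0.06 and -0.04, and the rapid stress median 0.06 and -0.01, all uncalled. A single locus passed without untreated wild-type replicate 2.

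With ABA, no locus passed between the arrays labelled gem1 and wild type (limma, 284 loci at an unadjusted p under 0.05, 0 and 1099 with the block) or between the overexpressor and wild type (249, 0 and 799 with the block), against 1630 expected by chance. On the gem1 arrays all 16 flavonoid genes were higher (median 0.46), with LDOX at 1.32 (SE 1.83), the 12 heat shock genes had a median of 0.56, with HSP17.6II at 1.73 (SE 1.05), the 17 gibberellin genes one of 0.20 and the 20 seed maturation genes one of -0.31, with CRU3 at -1.53 (SE 2.14). Their preset calls had adjusted p = 0.985, 0.397, 0.737 and 0.985 with an estimated correlation. In the overexpressor the seed maturation genes had a median of -0.29, the auxin genes 0.23 and the GEM-like family 0.22, with adjusted p = 0.986, 0.986 and 0.862 with an estimated correlation, and the GEM-like call ended with the block (adjusted p = 0.0727). No member of these lists passed. Without the dimmest 30% of loci the gem1 gibberellin (adjusted p = 0.111), seed maturation (0.109) and flavonoid (0.109) calls and the overexpressor auxin (0.152), seed maturation (0.146) and GEM-like (0.174) calls ended. Array weights ended the auxin and GEM-like calls (adjusted p = 0.0587 for both), and the GEM-like call ended with a variance trend (0.0576) and a second quantile normalization (0.104). With the block kept, each of these list medians kept its sign whichever array was left out. In gem1 seed maturation lay between -0.66 and -0.06, flavonoid between 0.37 and 0.64 and heat shock between 0.19 and 0.77. Seed maturation lay between -0.62 and -0.11 in the overexpressor. Without the block and without ABA-treated wild-type replicate 2 the seed maturation medians turned to 0.20 and 0.14 and the flavonoid (0.04), heat shock (0.49) and GEM-like (0.14) calls ended. The auxin median turned to -0.13 without ABA-treated wild-type replicate 1, where the gibberellin call (0.21) ended too, and was 0.03 without ABA-treated overexpressor replicate 2. The gem1 flavonoid (0.11), seed maturation (-0.05) and gibberellin (0.14) calls also ended without ABA-treated gem1 replicate 1, and the overexpressor seed maturation (-0.09) and GEM-like (0.05) calls without ABA-treated overexpressor replicate 1. The GEM-like call ended as well without either untreated wild-type (adjusted p = 0.0611) or overexpressor array (0.0583).

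The difference between the ABA responses of gem1 and wild type had 0 loci past the threshold (limma, 208 at an unadjusted p under 0.05, 0 and 886 with the block), and that between the overexpressor and wild type 0 as well (179, 0 and 662 with the block), against 1630 expected by chance. The flavonoid genes had median differences of 0.63 and 0.49, with all 16 values above 0 in both and none past the threshold. TT8, the bHLH regulator of the pathway, differed by 1.26 (SE 0.66) in gem1 and LDOX by 1.23 (SE 2.59) in the overexpressor, and the preset calls had adjusted p = 0.838 and 0.908 with an estimated correlation. The gem1 median was 0.17, 0.22, -0.05 and 0.26 without untreated wild-type replicate 1, ABA-treated wild-type replicate 2, untreated gem1 replicate 2 and ABA-treated gem1 replicate 1, and the overexpressor median 0.09, 0.16, 0.13 and 0.26 without the same wild-type arrays, untreated overexpressor replicate 2 and ABA-treated overexpressor replicate 1, all uncalled in fits without the block. With the block kept both preset calls held whichever of the 12 arrays was left out, with medians from 0.26 to 0.91 in gem1 and from 0.36 to 0.62 in the overexpressor. Over all 6 groups 14 of the 16 flavonoid genes were lower in replicate 2 than in replicate 1 past the threshold, with LDOX at -2.83. In simulated data for wild type without the block, 23.9% of loci changed by 1 on the log2 scale, 49.3% of those changed by 2 and 97% of those changed by 4 were recovered. For untreated gem1 against wild type the shares were 29.9%, 61.2% and 84.8%, and for the untreated overexpressor 35.8%, 55.2% and 86.4%. With the block they were 53.7%, 77.6% and 100% for wild type, 59.7%, 89.6% and 100% for gem1 and 59.7%, 94% and 100% for the overexpressor, with 4, 11 and 13 unchanged loci called, against 0, 0 and 1 without it. The simulation set no upper limit to the values, used the same replicate shift in every group and drew independent normal residuals. Real values end near 15.95. Real replicate deviations correlated unevenly between groups, from 0.44 to 0.88, where 1 shift for all groups would correlate them evenly. These shares may therefore be too high.

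Both altered lines were set against the same wild-type arrays. Across loci their differences from wild type correlated with r = 0.47 without ABA and 0.70 with ABA, and unchanged groups sharing those arrays gave 0.50 (0.48 to 0.52) in simulation. The covariance was 0.0116 and 0.024, against 0.0237 simulated. No locus was called in both by limma, with or without ABA, but none was called in either line, so this overlap says nothing. Residuals of real arrays combined in the same way gave r from -0.06 to 0.86 (5th to 95th percentile of 240 combinations). The wild-type arrays could not be split into parts of 2 arrays each. The covariance lay below the simulated value without ABA and 0.0004 above it with ABA, so the shared arrays alone could give it. With ABA r lay above the simulated range but within that of the real arrays. A change common to both lines is thus not shown. Without ABA r was 0.90 without either untreated wild-type array, 0.13 and 0.30 without untreated gem1 replicate 1 and 2, and 0.33 and 0.23 without untreated overexpressor replicate 1 and 2. With ABA it was 0.91 without ABA-treated wild-type replicate 1, 0.46 without ABA-treated gem1 replicate 1 and -0.04 without ABA-treated overexpressor replicate 1.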

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

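Tests chosen only after the results were seen were both weighings of the flavonoid pattern and the fits with an array left out and the replicate block kept. Some gene lists had a different ABA response in an altered line than in wild type, by the camera test of the difference itself with a preset correlation, and none of these calls held with an estimated correlation. In gem1 the flavonoid list differed by 0.63 (16 of 16 genes higher), seed maturation by -0.41 (2 of 20 genes higher), jasmonate response by 0.23 (19 of 21 higher), the gibberellin pathway by 0.21 (13 of 17 higher) and cell cycle by 0.18 (23 of 25 higher). Their adjusted p was 0.838 with an estimated correlation. In the overexpressor the flavonoid list differed by 0.49 (16 of 16 higher, adjusted p = 0.908 with an estimated correlation) and ABA synthesis and breakdown by 0.12 (12 of 16 higher, adjusted p = 0.851 with an estimated correlation). Without untreated wild-type replicate 1 all 7 preset calls ended, with medians of 0.17, -0.32, 0.09, 0.10 and 0.07 in the order above for gem1 and 0.09 and 0.15 for the overexpressor. Without ABA-treated wild-type replicate 2 the 5 gem1 medians were 0.22, 0.03, -0.04, 0.18 and 0.16 and the flavonoid median of the overexpressor 0.16, without ABA-treated gem1 replicate 1 they were 0.26, -0.24, 0.03, 0.18 and 0.13, and without untreated gem1 replicate 2 flavonoid, jasmonate, gibberellin and cell cycle gave -0.05, 0.03, -0.07 and -0.06, all uncalled. Seed maturation gave -0.58 without untreated gem1 replicate 1 and the gibberellin pathway 0.22 without ABA-treated wild-type replicate 1. In the overexpressor the flavonoid and the ABA synthesis medians were 0.13 and 0.16 without its untreated replicate 2, 0.26 and 0.14 without its ABA-treated replicate 1, and the latter 0.18 without ABA-treated wild-type replicate 1, all uncalled as well. These fits have no block, so that the difference between the replicate sets enters them. With the block kept, the 5 gem1 calls held in 12, 10, 10, 10 and 8 of the 12 fits with an array left out and the calls of the overexpressor in 12 and 4, the flavonoid medians lying between 0.26 and 0.91 in gem1 and between 0.36 and 0.62 in the overexpressor. The gibberellin and ABA synthesis calls also ended without the dimmest 30% of loci (0.27 and 0.10) and with a second quantile normalization (0.23 and 0.11). With the block salicylate defence in gem1 (0.16) and auxin in the overexpressor (-0.14) were called too (adjusted p = 0.732 and 0.924 with an estimated correlation).

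The flavonoid pattern was weighed further, as TT8, LDOX and DFR, a regulator and enzymes of anthocyanin synthesis, lead it. The lowest list median over both sets and both lines was 0.46, so the pattern is not confined to 1 replicate set. The list was chosen by its call in these same arrays, so this agreement is no independent support. Each set also holds a single array per group. The wild-type arrays shared by both differences remain a candidate explanation, since the responses of gem1 and the overexpressor, which use no wild-type array, differed by a median of 0.039. A difference by genotype stays open, as no test here separates it from the shared wild-type arrays.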

How the results depend on the processing

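Array number limits what can be called here, and without background flags the dim end cannot be judged. Of the fits in this part, those with an array left out and the block kept were chosen after seeing the data. With the replicate block the ABA counts were 1963, 1811 and 1910 (446, 475 and 506 without it) in wild type, gem1 and the overexpressor, and 4 lists were called in place of 2 for untreated gem1. The block ended the preset call of 2 of 60 lists, root hair growth in the untreated and the GEM-like family in the ABA-treated overexpressor, and it ended no other list's and no named gene's call. With only the groups of a contrast, 2 residual degrees of freedom gave 0 loci for ABA in all 3 genotypes, and all 60 named calls were lost by this construction. With a variance trend 1 locus passed between the untreated overexpressor and wild type, GEM feature 1 at 1.5 (adjusted p = 0.025 over loci). The values of 0.0769 under the block and 0.234 as reported are adjusted over all transcripts. Over loci, the lowest limma adjusted p of that contrast was 0.216 without the trend and 0.0707 with the block. Array weights left 1 list in place of 3 for the ABA-treated overexpressor, and ended named calls of CYP735A2 (adjusted p = 0.0676) and GIK (0.0512) in wild type, JAZ4 (0.0539) and TYRDC (0.0557) in gem1, and CYP735A2 (0.0588) and XTH31 (0.061) in the overexpressor. The variance trend ended that of TYRDC (0.057), and the quantile step that of GIK in wild type (0.0584) and the overexpressor (0.0564). Without the dimmest loci 1 list was called for gem1 with ABA, 1 for the overexpressor with ABA and 1 for the difference of the overexpressor's ABA response, and the quantile step also left 1 for the last. The cause was not tested. The size difference between gem1 and wild type at loci lower in the overexpressor was -0.0009 without the dimmest loci, 0.0535 with arrays shifted to 1 median and -0.0448 with the quantile step, against 0.0708. With an estimated correlation 0 lists were called in each of the 9 contrasts, the ABA-induced markers included, so these zeros do not weigh single lists. The whole-series table, every transcript feature and the 2-fold minimum moved no count by more than 1.5 times.

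Leaving out 1 array assumes that a lone array varies like the other groups, and without the block it also brings the difference between the replicate sets into the group of that array, so that the ranges that follow hold both. ABA counts ranged from 41 to 449 in wild type, 40 to 460 in gem1 and 86 to 467 in the overexpressor, the untreated genotype counts from 0 to 1 in both lines. The lists called ranged from 2 to 8 and from 1 to 12 for untreated gem1 and overexpressor, 4 to 9 and 2 to 6 with ABA, and 0 to 9 for both differences of the ABA response. Among the lists whose camera direction turned, the medians ranged from -0.4961 to 0.989 (flavonoid, ABA in gem1), -0.3557 to 0.1297 (cell cycle, untreated gem1), -0.0673 to 0.2698 (root hair growth, untreated overexpressor), -0.7348 to 0.1999 and -0.7026 to 0.1362 (seed maturation, gem1 and overexpressor with ABA), -0.1301 to 0.5642 (auxin, overexpressor with ABA), and -0.0415 to 0.5731 and -0.056 to 0.4643 (jasmonate and cell cycle, difference in gem1). Other medians changed sign with the direction of the test kept or its call lost, from -0.0768 to 0.8241 (rapid stress, ABA in wild type), -0.6477 to 0.0076 and -0.2759 to 1.4071 (root tissue and seed maturation, ABA in gem1), -0.104 to 0.3672 and -0.2595 to 0.8816 (jasmonate and flavonoid, ABA in the overexpressor), -0.0112 to 0.7817 and -0.765 to 0.0556 (rapid stress and flavonoid, untreated overexpressor), and -0.067 to 0.5176, -0.804 to 0.0311 and -0.0504 to 1.4351 (gibberellin, seed maturation and flavonoid, difference in gem1). Of 60 called lists, 18 had a median that changed sign with an array left out, and 42 one that changed sign or moved by more than 1.5 times. With the block kept 5 changed sign and 35 changed sign or moved by more than 1.5 times. Of 720 preset tests of these lists, 657 were called in the same direction and 63 were not. The 63 include tests of 2 lists whose call the block had already ended with all arrays in. These were root hair growth (untreated overexpressor) and the GEM-like family (ABA-treated overexpressor), called in 2 and 6 of 12 fits. Test directions turned in cell cycle (-0.2592 to 0.0644, untreated gem1), root hair growth (-0.155 to 0.3229, untreated overexpressor), seed maturation (-0.6566 to -0.0591, gem1 with ABA) and cell cycle (-0.0013 to 0.3408, difference in gem1). The ABA counts then ranged from 371 to 2506 in wild type, 348 to 1730 in gem1 and 437 to 1928 in the overexpressor, and the counts between genotypes from 0 to 2. Without the block, size differences of the ABA response ranged from -0.15 to 0.2851 and 0.0327 to 0.4509 for gem1 minus wild type at loci higher and lower in the overexpressor, from -0.1167 to 0.242 for the overexpressor minus wild type and from -0.175 to 0.1461 for the overexpressor minus gem1, both at higher loci. The correlation of the gem1 and overexpressor differences ranged from 0.1268 to 0.9016 without ABA and from -0.0427 to 0.9063 with ABA. Over all 12 arrays left out in turn 639 list calls held, 72 were lost and 9 turned in test direction, and 454 calls of named genes held and 266 were lost with the same sign.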

Other observations

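Tests chosen only after the result was seen were those of the ABA or stress state over all and over ABA-responsive loci, the harvest hour, the mislabelled sample and both counts of splits, and the non-robust form of the smooth curve, used in place of a robust one that gave an uninterpretable -0.371%. Apart from ABA and genotype, the replicate 1 and replicate 2 seedlings differed in known gene groups. Flavonoid genes were lower in replicate 2 (median -1.02, 14 of 16 past the threshold), with LDOX at -2.83 (adjusted p = 0.00148) and DFR at -2.27 (adjusted p = 0.000534). Early auxin genes were higher (median 0.60, 14 of 23 past the threshold), jasmonate genes lower (-0.36, 15 of 21) and salicylate defence genes lower (-0.44, 10 of 16). Among clock genes, the evening genes BOA (-2.49, adjusted p = 0.000296), PRR3 (-1.97), ELF4 (-1.63), PCL1 (-1.16) and TOC1 (-0.76) were lower in replicate 2, and the morning genes PRR9 (2.43, adjusted p = 0.000017), CCA1 (1.65), LHY (1.19) and RVE8 (0.81) were higher, each in 6 of 6 groups. Of the 17 clock genes 4 did not pass, the morning gene RVE1 (-0.15, lower in 3 of 6 groups, adjusted p = 0.639), GI (-0.10, adjusted p = 0.0993), PRR5 (-0.0043) and ZTL (0.03). Of 32627 loci, 15350 passed for the replicate term of the limma block fit.

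The design gives no group that sets the state of the plants apart from the replicate number, so explanations of this difference from the plants were compared with the same arrays only. A smooth curve on mean signal level explained 3.91% of the variance of the difference, so little of it followed that level in these values. RMA equalises the distributions of arrays and so takes out much of such a trend beforehand. In every group the first quartile was still higher and the median lower in replicate 2. A technical difference between the replicate sets is thus not excluded. A different ABA or stress state of the untreated plants stays open. Over all loci the untreated wild-type replicate difference correlated with the overexpressor's ABA response at r = 0.0646, a test that dilutes the ABA-responsive loci and was at first read as excluding this state. At loci higher after ABA in another genotype, untreated replicate 1 exceeded replicate 2 by medians of 0.25 in wild type, 0.21 in gem1 and 0.1062 in the overexpressor, and the ABA-induced markers went the same way. At loci lower after ABA the medians were 0.02, 0.0536 and -0.09, which go both ways and decide nothing. A different hour of harvest may contribute. The median absolute difference of the clock genes, 0.76, lay at percentile 100 of 10000 expression-matched random lists, whose median was 0.12. No other list was put through this test, and flavonoid genes differed by a median of -1.02 and auxin genes by 0.60. The percentile therefore does not set the hour apart from other differences between the replicate sets. Neither hour nor day of harvest is given in the sources used here.

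GEM feature 2 was higher by 1.94 on the arrays labelled gem1 and high on replicate 1 of the overexpressor, where feature 1 rose on all 4 arrays. A wild-type sample mislabelled as overexpressor replicate 2 is argued against, since the lower of its feature 1 values lay 1.39 above the wild-type mean. Cross-hybridisation with the GEM-like relatives examined is argued against, since the highest difference among 8 features of these 7 loci was 0.21, in AT5G23360. AT4G40100, also listed beforehand as a relative, was not among them. Transcription running on into a neighbour is argued against, since AGP2 differed by -0.12 and PFK5 by -0.0231. These loci cannot show whether transcription within GEM itself raises feature 2. What raises feature 2 on the arrays labelled gem1 and in 1 replicate of the overexpressor (11.36 and 9.56 without ABA) stays open.

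Averaged over treatments, an alternative chosen after seeing the data, GEM was the single locus that passed between the overexpressor and wild type (1.42, SE 0.10, adjusted p = 0.0253, and 0.00892 with the block, higher on 4 of 4 arrays). Of the 18 splits of the arrays within treatment 2 gave as many loci, the real one with 1 and the split by replicate number with 1, which was also the highest other. For gem1 no locus passed (limma, 184 at an unadjusted p under 0.05, 0 with the block), so that all 18 splits give as many by construction and their number decides nothing. The highest other, the split by replicate number, gave 8797, which points to a structure of the samples by replicate number. The 18 splits are too few for a share under 0.05.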
